A study of Mus musculus with 17 samples.

How the data were processed

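The series holds 17 single-channel Affymetrix arrays of total RNA from mouse plasmacytoid dendritic cells. The cells came from the bone marrow of C57BL/6 mice, were enriched by removing other cells magnetically and were then sorted as CD11c-intermediate, B220-positive and Siglec-H-positive. They were cultured in 6 groups. Medium had 2 arrays (replicates 1 and 3), and LIF, CpG-A, CpG-A + LIF, CpG-B and CpG-B + LIF had 3 arrays each. LIF (leukaemia inhibitory factor, a cytokine that signals through gp130 and STAT3) was given at 10 ng/ml, 1 h before CpG where both were used, for 20 to 24 h in total. CpG-A and CpG-B, unmethylated DNA oligonucleotides that trigger TLR9, were given at 6 µg/ml for 19 to 23 h. RNA was isolated with a column kit for small samples. The submitters' processing notes name RMA, a method that corrects background, normalizes between arrays and summarises probes. Its version, the level of summarization and the other tools are not given in the sources used here.

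The deposited table gives each value as the digits of a linear RMA intensity from which the decimal mark has been lost. All but 1 of its 419560 cells are whole numbers of at most 10 digits, and 1 cell kept its mark (251.19). Of the cells, 90.0% have 10 digits and 9.0% have 9. The leading digit is 1 in 32.0% of cells and 9 in 5.0%, as happens for linear values spread over several powers of 10. The power of 10 of each value is therefore unknown, and a log2 value is known only up to whole multiples of log2(10), a period of 3.32. Expression levels, signal over background and the size of large changes cannot be recovered from such a table.

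A difference between groups was therefore taken as the nearest reading, the one between -1.66 and 1.66 on the log2 scale. Group means were circular means over the period, and each array's deviation was taken as the shortest way to its group mean. A true change over 3.16-fold shows up as a smaller change, often of the opposite sign, and a change of about 10-fold shows up as none. A gene was said to read higher or lower when its called reading was at most 1.11 in size (2.15-fold), because the other reading is then a change of at least 4.64-fold in the opposite direction. For larger readings the direction was left open and both readings are given. For the mean of the 3 LIF effects, and for interactions, every background reading had to be within the limit. An interaction is the difference of 2 nearest readings and was not folded again. This limit on direction was chosen after seeing the data. A model of how the readings of called genes thin out with size put the share of misread directions among called readings within the limit at 4.77% for CpG-A vs medium (95% interval 3.95 to 6), 4.65% for CpG-B vs medium, 7.13% for LIF vs medium (3.19 to 17.2) and 1.27% for CpG-A vs CpG-B. At a reading of 1 the shares were higher, at 13% for increases and 4.51% for decreases in CpG-A vs medium. The model assumed that true increases and decreases thin out at the same steady rate, and it was fitted to the nearest readings themselves. It cannot see a group of strongly changed genes that breaks this assumption, so the true shares may be higher. A gene that was not called is not thereby unchanged.

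The table holds 24680 probe sets. Of these, 21354 carry exactly 1 gene symbol, 1275 carry several and 2051 have no listed gene, and only the first kind was used. Each gene was represented by the probe set with the most listed accessions, since the planned choice by mean intensity needs the lost levels. This left 19751 genes, 893 of which had more than 1 probe set. No gene was filtered out. The median standard deviation within groups was 0.19 on the log2 scale (5th to 95th percentile 0.107 to 0.358). For 87.7% of genes, all 17 arrays could be placed within 3.16-fold by choice of each value's lost decimal place. The true spread of these arrays is unknown, since larger differences can look as small. Arrays give no counting depth, and the number of arrays limits the precision.

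Differences were tested with limma 3.58.1 in R 4.3.3, with 1 coefficient per group over all 17 arrays (11 residual degrees of freedom), moderated variances and Benjamini-Hochberg adjustment over all 19751 genes. A gene was called at an adjusted p under 0.05. The comparisons were CpG-A vs medium, CpG-B vs medium, LIF vs medium, LIF added to CpG-A, LIF added to CpG-B, CpG-A vs CpG-B, each CpG with LIF vs LIF alone, the mean of the 3 LIF effects, the interactions of LIF with each CpG, and the difference between the LIF effects under the CpGs. The p-values measure the spread between cultures or arrays, which may be technical. The labels do not say whether replicates are separate mice, and RNA from pools of cells cannot be told from single animals here.

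Each of 27 gene lists was tested with camera, a competitive test of a list against all other genes, at a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Adjustment was over the lists of a comparison. The rotation test fry was run as a further alternative, in its directional and its mixed form. The lists cover type I and III interferon genes, interferon-stimulated genes, inflammatory cytokines and chemokines, co-stimulation and dendritic cell maturation, MHC class I and class II presentation, plasmacytoid dendritic cell identity, endosomal TLR signalling, LIF receptor and JAK-STAT components, STAT3 targets and feedback, NF-kB targets and feedback, the E-protein and Id factor axis, cell cycle, apoptosis and survival, the unfolded protein response and secretion, glycolysis, cholesterol synthesis, oxidative phosphorylation, and stress and immediate early genes. They also cover markers of conventional dendritic cells, monocytes and macrophages, neutrophils and their precursors, B cells, plasma cells, T and NK cells, erythroid and megakaryocyte cells, and basophils and mast cells. A further list of sex-linked genes served only to check for mixed cultures.

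The groups, comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the largest increases and decreases among called genes whose arrays do not overlap between groups, up to 4 members of each list with a call, up to 2 members of each list without one, and 22 genes of prior interest in any comparison. Gene models, receptor segments and small RNAs were passed over. Its condition on level could not be applied, and its largest changes were ranked among readings within the limit on direction, an adaptation made after seeing the data. These genes sit at the largest readable sizes, where misreading is most frequent.

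The numbers shared by arrays of different groups were checked as possible pairs through the correlation, across genes, of their deviations from the group means. CpG-B with CpG-B + LIF gave 0.126, 0.243 and 0.143 for replicates 1, 2 and 3. Over all 40 pairs with the same number the mean was 0.035, against -0.017 for different numbers, whose highest value was 0.108, and 14 of 17 arrays had their best match in other groups under their own number, a hint from the data and not from the design. The main tests use no pairing in any comparison. For CpG-B + LIF vs CpG-B, where the number may mark a pair, the count and some genes with the replicate as a block are given beside the unpaired results.

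Alternatives tried were the replicate number as a fixed or random block, array weights, centring of arrays, the mean of a gene's probe sets, only the arrays compared, an added fold threshold and leaving out each array. Leaving out 1 of the 2 medium arrays rests on the assumption that the other varies like the rest. Chosen after seeing the data were readings unfolded at the widest gap between the 17 arrays, and a robust variance prior. Also chosen then were a narrower definition of raised genes, and the LIF effect averaged without the medium and LIF groups. A last such setting kept only genes whose arrays could all be placed within 3.16-fold by choice of decimal place, whatever their true spread. A filter on dim probe sets, repeated quantile normalization, a variance trend with intensity and a larger fold for raised genes all need the lost levels or larger readings and were not run. Other groupings of the arrays were tested with up to 100 splits. The procedure was tested on simulated data, with 50 of 19751 genes changed at each size. In LIF vs medium it called 38 of 50 genes changed by 1 on the log2 scale and 2 of 50 changed by 3. For the mean of the 3 LIF effects it called 16 of 50 genes changed by 3, all 16 in the wrong direction, so large true changes can be misread there too. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.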

Results

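Gene expression was measured in sorted bone marrow plasmacytoid dendritic cells, the dendritic cell type that makes large amounts of type I interferon after sensing nucleic acids through TLR7 and TLR9. Cells were kept in medium (2 arrays) or given LIF, CpG-A, CpG-A + LIF, CpG-B or CpG-B + LIF (3 arrays each). CpG-A is known for inducing interferon, and CpG-B for driving maturation and cytokines such as TNF and IL-6. The design asked how LIF changes resting cells and cells responding to each CpG. Because the decimal mark of the deposited intensities is lost, each difference between 2 groups is given as its nearest reading on the log2 scale ± SE, and as 2 possible readings where the direction stays open. The sample sizes behind each SE are those of the groups compared.

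CpG-A vs medium asked what CpG-A does to resting cells (n = 3 and 2). As lists, genes of the unfolded protein response and secretion and of MHC class I presentation leaned to higher readings and cell cycle genes to lower ones, and some of their members stayed open in direction. Of the 9 lists called there, 0 kept their call with an estimated correlation between genes. Manf, an endoplasmic reticulum stress factor, read 0.93 ± 0.11 higher, and Pdia3, a chaperone of the peptide loading complex, 0.99 ± 0.12 higher. Tlr9, the receptor for CpG DNA, read 0.93 ± 0.13 higher, and Stat3, the main transducer of LIF signals, 0.84 ± 0.12 higher. Among cell cycle genes, cyclin A (Ccna2) read -0.93 ± 0.17, the mitotic motor Kif11 -1.01 ± 0.22 and the anaphase activator Cdc20 -0.81 ± 0.15. Siglech, a surface receptor of this cell type and part of the sorting gate, read -0.58 ± 0.15 (adjusted p = 0.00941).

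Of 19751 genes, 3300 were called in CpG-A vs medium, of which 970 read higher, 1413 read lower and 917 stayed open in direction. The unfolded protein response and secretion list had 20 of 24 members called (22 adjusted over the list alone), 13 of them higher, 2 lower and 5 open, with a median reading of 0.684. Its camera adjusted p was 1.080e-06, with adjusted p = 0.124 with an estimated correlation. In MHC class I presentation, 11 of 18 members were called (13 adjusted over the list alone), 6 higher, 0 lower and 5 open, with adjusted p = 1.060e-05, and adjusted p = 0.124 with an estimated correlation. Tap1, which carries peptides into the endoplasmic reticulum, read 1.55 ± 0.15 (or -1.77). Cell cycle members were called in 11 of 29 cases (13 adjusted over the list alone), 1 higher, 9 lower and 1 open, with adjusted p = 0.025, and adjusted p = 0.515 with an estimated correlation. In cholesterol synthesis, 5 of 19 members read higher (5 adjusted over the list alone; adjusted p = 0.0223, and adjusted p = 0.515 with an estimated correlation). Among B cell markers, 7 of 17 were called (9 adjusted over the list alone), 1 higher, 3 lower and 3 open, with a median of -0.178 and adjusted p = 0.0344, and adjusted p = 0.124 with an estimated correlation.

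Several groups known to respond strongly to CpG could be seen to change in CpG-A vs medium while their direction stayed open. In interferon-stimulated genes, 30 of 43 members were called (35 adjusted over the list alone), 8 higher, 7 lower and 15 open, and the mixed fry test gave adjusted p = 8.450e-16. Stat2, a transducer of interferon signals, read -1.60 ± 0.14 (or 1.73), and Ifitm3, an antiviral membrane protein, 1.65 ± 0.19 (or -1.67). NF-kB targets and feedback had 18 of 22 members called (18 adjusted over the list alone), 6 higher, 1 lower and 11 open, with camera adjusted p = 0.00288, and adjusted p = 0.124 with an estimated correlation. Within that list the feedback inhibitor Tnfaip3 read -1.56 ± 0.16 (or 1.76) and Nfkb2 -1.64 ± 0.13 (or 1.68). The gene of the cytokine TNF read -1.01 ± 0.20, or 2.31 when Tnf was unfolded at the widest gap between arrays, a setting chosen after seeing the data. Id2, an inhibitor of E proteins, read 1.51 ± 0.18 (or -1.81), the LIF receptor gene Lifr 1.26 ± 0.12 (or -2.06), and Il6st, which encodes its partner gp130, -1.57 ± 0.15 (or 1.75). Of 14 type I and III interferon genes, 2 were called (2 adjusted over the list alone). Ifnl2, a type III interferon, read higher at 1.06 ± 0.25 (or -2.26), and Ifna12 read lower at -1.08 ± 0.25 (or 2.24), both near the limit on direction. Ifna4 (-0.19 ± 0.35) and Ifnb1 (0.48 ± 0.26) were not called, which leaves open changes near 10-fold. Ifna genes are near-identical copies, so their probe sets may share signal.

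Lists of endosomal TLR signalling (12 of 28 members called, 13 adjusted over the list alone), STAT3 targets (11 of 30, 12 adjusted over the list alone) and stress genes (9 of 19, 11 adjusted over the list alone) were also called upward in CpG-A vs medium. Their camera adjusted p-values were 0.0223, 0.0224 and 0.0224, and each list lost its call, at adjusted p = 0.124, adjusted p = 0.19 and adjusted p = 0.156 with an estimated correlation. Without medium replicate 1 the comparison called 2128 genes, and the call of Ifnl2 was lost (0.92, adjusted p = 0.0793; range over alternatives 0.00108 to 0.0793). The call of Siglech was lost without medium replicate 1 (-0.58, adjusted p = 0.0641) and without medium replicate 3 (-0.57, adjusted p = 0.0659; range over alternatives 0.00429 to 0.0659).

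CpG-B vs medium asked the same of CpG-B (n = 3 and 2). As lists, MHC class I genes and NF-kB targets leaned to higher readings and the E-protein and Id factor axis to lower ones, and some of their members stayed open in direction. Relb, an NF-kB subunit of dendritic cell maturation, read 1.08 ± 0.18 higher, and Tapbp, which tethers MHC class I to the peptide transporter, 1.02 ± 0.12 higher. Spib, a transcription factor of this cell type, read -0.74 ± 0.16 (adjusted p = 0.0029). The LIF receptor gene Lifr read -0.62 ± 0.12 and its partner Il6st -1.05 ± 0.15. The cholesterol synthesis enzymes Fdps and Hsd17b7 read 1.02 ± 0.19 and 1.00 ± 0.20 higher.

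In CpG-B vs medium 3795 genes were called, of which 1371 read higher, 1383 read lower and 1041 stayed open. MHC class I presentation had 13 of 18 members called (14 adjusted over the list alone), 9 higher, 0 lower and 4 open, with camera adjusted p = 6.000e-09 and adjusted p = 0.0448 with an estimated correlation. NF-kB targets and feedback had 13 of 22 called (14 adjusted over the list alone), 5 higher, 0 lower and 8 open, with adjusted p = 2.710e-08 and adjusted p = 0.0144 with an estimated correlation. Its feedback inhibitors Nfkbia and Tnfaip3 read 1.55 ± 0.18 (or -1.77) and 1.51 ± 0.16 (or -1.81). In the E-protein and Id factor axis, 14 of 19 members were called (14 adjusted over the list alone), 1 higher, 7 lower and 6 open, with a median of -0.743, adjusted p = 5.100e-05, and adjusted p = 0.0367 with an estimated correlation. Tcf4, the master transcription factor of plasmacytoid dendritic cells, read -1.41 ± 0.13 (or 1.91), the lymphoid factor Ikzf1 -1.42 ± 0.16 (or 1.90) and the growth factor receptor Flt3 -1.59 ± 0.17 (or 1.73). These 3 lists were the ones that kept their call with an estimated correlation.

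The other lists called in CpG-B vs medium lost their call with an estimated correlation. Plasmacytoid dendritic cell identity had 16 of 28 members called (19 adjusted over the list alone), 2 higher, 6 lower and 8 open, with adjusted p = 0.00341, and adjusted p = 0.151 with an estimated correlation. Siglech read 1.40 ± 0.15 (or -1.92). The unfolded protein response list had 19 of 24 called (20 adjusted over the list alone; adjusted p = 3.280e-06, and adjusted p = 0.108 with an estimated correlation), with Manf at 1.14 ± 0.11 (or -2.18). In co-stimulation and maturation, 15 of 24 members were called (16 adjusted over the list alone), 7 higher and 8 open, with adjusted p = 0.0205, and adjusted p = 0.232 with an estimated correlation. Cholesterol synthesis had 8 of 19 called (10 adjusted over the list alone), 7 higher and 1 lower, with adjusted p = 0.00341, and adjusted p = 0.399 with an estimated correlation. STAT3 targets (10 of 30, 11 adjusted over the list alone) gave adjusted p = 0.00341, and adjusted p = 0.108 with an estimated correlation. The STAT3 target kinase Pim1 read 1.47 ± 0.20 (or -1.85). B cell markers (5 of 17, 5 adjusted over the list alone) had a median of -0.324 and stress genes (9 of 19, 10 adjusted over the list alone) one of 0.119. Both had a camera adjusted p of 0.0276, with adjusted p = 0.108 and adjusted p = 0.151 with an estimated correlation. Oxidative phosphorylation (1 of 28, 1 adjusted over the list alone) had a median of 0.14 (adjusted p = 0.04, and adjusted p = 0.52 with an estimated correlation).

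As with CpG-A, the strongest known targets stayed open under CpG-B. Interferon-stimulated genes had 31 of 43 members called, 10 higher, 8 lower and 13 open, with a mixed fry adjusted p of 3.660e-14. The cytokine genes Tnf and Il6 read 1.60 ± 0.20 (or -1.72) and -1.29 ± 0.29 (or 2.03), and Irf7, the master regulator of interferon genes, -1.45 ± 0.21 (or 1.87). Ifna4 (0.21 ± 0.35) and Ifnb1 (-0.45 ± 0.26) were not called. Without medium replicate 3 the comparison called 2451 genes, and the call of Spib was lost (-0.56, adjusted p = 0.0827; range over alternatives 0.00224 to 0.0827).

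CpG-A vs CpG-B compared the classes of oligonucleotide directly (n = 3 and 3). As lists, interferon-stimulated genes leaned to higher readings with CpG-A, as did genes of plasmacytoid dendritic cell identity and TLR signalling. MHC class II, glycolysis, cell cycle and oxidative phosphorylation genes leaned to higher readings with CpG-B. Of the 10 lists called, 0 kept their call with an estimated correlation. The interferon transducer Stat2 read 0.85 ± 0.13 higher with CpG-A, the antiviral GTPase Mx1 0.77 ± 0.14, Tcf4 1.03 ± 0.11 and Spib 1.01 ± 0.15. With CpG-B, the class II chain H2-Ab1 read higher (-1.07 ± 0.20 for CpG-A minus CpG-B), as did its chaperone Cd74 (-0.79 ± 0.16), the glycolytic enzyme Pgam1 (-0.97 ± 0.14) and the replication helicase subunit Mcm5 (-1.10 ± 0.18).

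In CpG-A vs CpG-B 2560 genes were called, of which 873 read higher with CpG-A, 1212 read lower and 475 stayed open. Of 43 interferon-stimulated genes, 26 were called (34 adjusted over the list alone), 25 higher, 0 lower and 1 open, and 41 had a nearest reading above 0. The list had a median of 0.535 and camera adjusted p = 1.930e-14, with adjusted p = 0.11 with an estimated correlation. The interferon-induced genes Oasl2 and Sp100 read 0.87 ± 0.16 and 0.58 ± 0.11 higher, and the chemokine Cxcl10 0.95 ± 0.20. In plasmacytoid dendritic cell identity, 19 of 28 members were called (21 adjusted over the list alone), 10 higher, 1 lower and 8 open, with adjusted p = 1.410e-07, and adjusted p = 0.0736 with an estimated correlation. Siglech read 1.34 ± 0.13 (or -1.98) and the checkpoint receptor Lag3 1.17 ± 0.13 (or -2.15). The nearest readings of Siglech among medium, CpG-A and CpG-B do not add up, so they cannot all hold. Endosomal TLR signalling had 13 of 28 called (15 adjusted over the list alone), 11 higher and 2 lower, with adjusted p = 6.880e-04, and adjusted p = 0.0736 with an estimated correlation. Tlr9, Tlr7 and the lysosomal transporter Slc15a4 read 0.56 ± 0.11, 0.70 ± 0.14 and 0.99 ± 0.16 higher. The E-protein and Id factor axis had 7 of 19 called (8 adjusted over the list alone), 6 higher and 1 lower, with adjusted p = 0.00281, and adjusted p = 0.101 with an estimated correlation. NF-kB targets had 7 of 22 called (8 adjusted over the list alone), 5 higher and 2 open, with adjusted p = 0.0126, and adjusted p = 0.162 with an estimated correlation. Rel and the adhesion gene Icam1 read 0.73 ± 0.13 and 0.83 ± 0.15 higher.

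**Figure D1:**
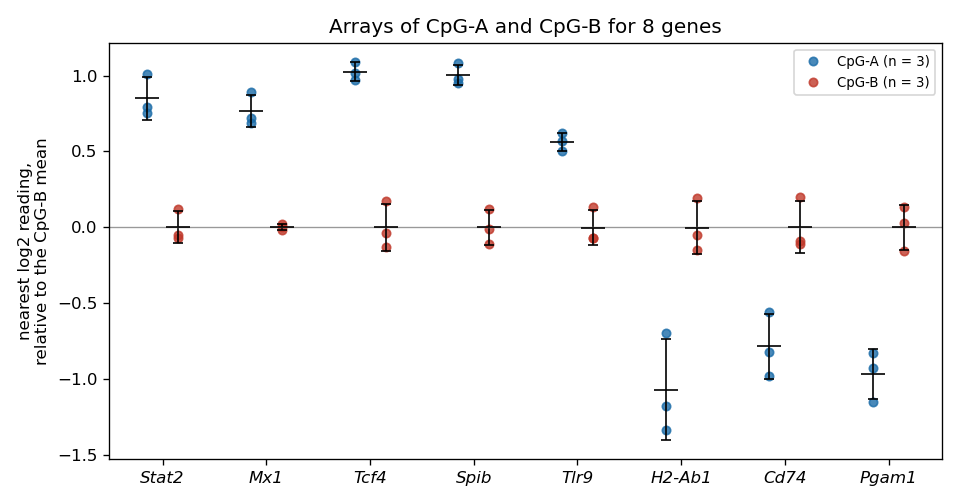
Nearest log2 readings of 8 genes in the arrays of CpG-A and CpG-B (n = 3 each), relative to the CpG-B mean, with group means and SD. Stat2, Mx1, Tcf4, Spib and Tlr9 lie higher in every CpG-A array, and H2-Ab1, Cd74 and Pgam1 lie lower in every one.

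Among the groups that leaned to higher readings with CpG-B than with CpG-A, MHC class II presentation had 7 of 14 members called (8 adjusted over the list alone), 4 lower with CpG-A and 3 open, with a median of -0.626. Its adjusted p was 1.580e-04, with adjusted p = 0.129 with an estimated correlation. Glycolysis had 8 of 17 called (9 adjusted over the list alone), 1 higher with CpG-A, 5 lower and 2 open, with adjusted p = 0.00281, and adjusted p = 0.101 with an estimated correlation. Cell cycle had 9 of 29 called (10 adjusted over the list alone), 0 higher, 4 lower and 5 open, with adjusted p = 0.00281, and adjusted p = 0.455 with an estimated correlation. Oxidative phosphorylation had 3 of 28 called, all lower with CpG-A (0 adjusted over the list alone), and 25 with a nearest reading below 0. It gave adjusted p = 4.620e-04, and adjusted p = 0.38 with an estimated correlation. The unfolded protein response had 5 of 24 called (6 adjusted over the list alone; adjusted p = 0.0475, and adjusted p = 0.473 with an estimated correlation). The chemokine receptor Ccr7, which guides mature dendritic cells to lymph nodes, read -1.36 ± 0.18 (or 1.96), and Lifr -1.44 ± 0.11 (or 1.88). The nearest readings of Lifr among medium, CpG-A and CpG-B do not add up, so they cannot all hold. Stat3 read 0.46 ± 0.11 higher with CpG-A. Ifnb1 read higher at 0.92 ± 0.23 (or -2.40, adjusted p = 0.012) and Ifnab lower at -0.92 ± 0.23 (or 2.40). The direction stayed open for Ifna12 at -1.14 ± 0.23 (or 2.18) and Ifna2 at -1.27 ± 0.33 (or 2.05). The call of Ifnb1 was lost without CpG-B replicate 1 (0.76, adjusted p = 0.0742), CpG-A replicate 1 (0.86, adjusted p = 0.0513) and CpG-A replicate 3 (0.85, adjusted p = 0.0524), within a range over alternatives of 0.00692 to 0.0742. That of Ifnab was lost without CpG-A replicate 2 (-0.79, adjusted p = 0.0551; range 0.00617 to 0.0551).

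LIF vs medium asked what LIF does to resting cells (n = 3 and 2). Called genes included some of the STAT3 target list, and plasmacytoid dendritic cell identity genes tended to lower readings as a list. Of the 9 lists called, 0 kept their call with an estimated correlation. Socs3, the feedback inhibitor of LIF and gp130 signalling, read -1.49 ± 0.18 (or 1.83, 3.56-fold higher), and the acute phase gene Saa3 1.57 ± 0.24 (or -1.75). Il4ra, a cytokine receptor gene in the STAT3 target list, read 0.79 ± 0.16 higher, and Bcl3, a nuclear IkB protein, 1.17 ± 0.23 (or -2.15). The TLR adaptor Myd88 read 0.85 ± 0.16 higher, and the stem cell factor receptor Kit 1.02 ± 0.20 higher. Id2, an inhibitor of E proteins that opposes this cell type, read 1.24 ± 0.18 (or -2.08), and the scavenger receptor Msr1 1.31 ± 0.24 (or -2.01).

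In LIF vs medium 160 genes were called, of which 54 read higher, 44 read lower and 62 stayed open. The largest readable increases included Dennd4a (1.10 ± 0.17), the T cell and dendritic cell surface gene Cd8a (1.10 ± 0.17), the inhibitory receptor Cd300a (1.06 ± 0.24) and glutathione reductase, Gsr (1.01 ± 0.15). The decreases included Tmem163 (-1.07 ± 0.17), the kinase Sik1 (-1.04 ± 0.16), the growth factor receptor Egfr (-0.97 ± 0.18) and the interferon-induced chemokine Cxcl10 (-1.06 ± 0.22). Unfolded at the widest gap, Cd300a read -1.16. The probe sets of Socs3 disagreed. The other one read 0.88 (unadjusted p = 0.0063), and with the mean of both the call was lost (-0.31, adjusted p = 0.684; range over alternatives 3.030e-04 to 0.684).

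In STAT3 targets and feedback, 4 of 30 members were called for LIF vs medium (9 adjusted over the list alone), 1 higher and 3 open, with a median of 0.201. The list gave adjusted p = 0.00152, and adjusted p = 0.289 with an estimated correlation. Of 43 interferon-stimulated genes, 2 were called (13 adjusted over the list alone), the RNA sensor Oas3 at 0.94 ± 0.17 and Oas2 at 1.66 ± 0.33 (or -1.66), and 30 had nearest readings above 0. Their list gave adjusted p = 3.150e-06, and adjusted p = 0.332 with an estimated correlation. Monocyte and macrophage markers had 16 of 21 nearest readings above 0 and 1 call (1 adjusted over the list alone; adjusted p = 0.00348, and adjusted p = 0.289 with an estimated correlation). Basophil and mast cell markers had 9 of 10 above 0 and 1 call (1 adjusted over the list alone; adjusted p = 0.00348, and adjusted p = 0.332 with an estimated correlation). Co-stimulation and maturation had 1 call in 24, Cd69 at 1.30 ± 0.20 (or -2.02), with adjusted p = 0.00348, and adjusted p = 0.289 with an estimated correlation. Cytokines and chemokines had 3 calls in 30 (5 adjusted over the list alone), among them the inflammatory cytokine Il1b at 1.25 ± 0.25 (or -2.07), with adjusted p = 0.0209, and adjusted p = 0.307 with an estimated correlation.

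Plasmacytoid dendritic cell identity had 1 call in 28 for LIF vs medium (9 adjusted over the list alone), and 21 members had nearest readings below 0, with a median of -0.166. The list gave adjusted p = 0.014, and adjusted p = 0.307 with an estimated correlation. MHC class II presentation, with the lysosomal protease Lgmn at 0.86 ± 0.18, and stress genes were called upward at medians of 0.134 and 0.151. Their adjusted p-values were 0.0243 and 0.0443, with adjusted p = 0.345 and adjusted p = 0.307 with an estimated correlation. Siglech (-0.02 ± 0.15), Tcf4 (-0.18 ± 0.13), Stat3 (0.20 ± 0.12), Lifr (0.31 ± 0.12) and Il6st (-0.08 ± 0.15) were not called. The comparison rested on few arrays: without medium replicate 3 it called 16 genes, without medium replicate 1 it called 34, without LIF replicate 1 it called 88, and with only the arrays compared it called 17. Of 31 called genes of the naming rule followed through the leave-outs, Socs3 alone kept its call without each array in turn. Leaving out medium replicate 3 ended most of the other calls. It also turned the Socs3 reading from -1.49 to 1.55 through the fold.

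CpG-A + LIF vs CpG-A asked how LIF changes the CpG-A response (n = 3 and 3). Interferon-stimulated genes, plasmacytoid dendritic cell identity genes and MHC class I genes leaned to lower readings as lists, without a called member, and monocyte and macrophage markers to higher ones. Of the 6 lists called, 0 kept their call with an estimated correlation. In type I and III interferon genes, 9 of 14 readings were too large for a direction. Of the nearest readings 12 were below 0, with a median of -1.20 and a mean of -0.711. Ifna12 was the 1 gene called (-1.58 ± 0.23, or 1.74; adjusted p = 0.0337), and 9 members were called adjusted over the list alone. Ifnb1 read -1.22 ± 0.23 (or 2.10; adjusted p = 0.0998), Ifnab -1.31 ± 0.23 (or 2.02; adjusted p = 0.0646) and Ifna4 -1.61 ± 0.32 (or 1.71; adjusted p = 0.104). Against these, Ifna11, chosen after its values were seen, read 1.65 ± 0.34 (or -1.67).

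The interferon list gave camera adjusted p = 5.730e-11 for LIF under CpG-A, and adjusted p = 0.0892 with an estimated correlation. Its median reading was -0.10 without CpG-A + LIF replicate 1, -0.23 without CpG-A replicate 2, -0.68 without CpG-A replicate 1 and -0.77 without CpG-A + LIF replicate 3. In the first 2 of these cases 3 members passed a size of 1.66 and so changed sign through the fold, and the median size of the readings was 1.33 and 1.40, against 1.26 with all arrays. In interferon-stimulated genes, 0 of 43 members were called by limma (0 adjusted over the list alone), yet 40 had nearest readings below 0, with a median of -0.231. The list gave adjusted p = 3.860e-10, and adjusted p = 0.32 with an estimated correlation. The interferon feedback protease Usp18 read -0.33 ± 0.13 and Stat2 -0.29 ± 0.13. Plasmacytoid dendritic cell identity had 23 of 28 readings below 0 and 0 calls (3 adjusted over the list alone), with adjusted p = 2.000e-05, and adjusted p = 0.0892 with an estimated correlation. The pyrimidine catabolic enzyme Upb1 read -0.84 ± 0.16 (adjusted p = 0.0998) and Siglech -0.19 ± 0.13. MHC class I presentation had 15 of 18 readings below 0 and 0 calls (0 adjusted over the list alone), with H2-Q4 at -0.52 ± 0.16 and the immunoproteasome subunit Psmb9 at -0.32 ± 0.13. It gave adjusted p = 6.180e-04, and adjusted p = 0.321 with an estimated correlation. Monocyte and macrophage markers had 19 of 21 readings above 0 and 0 calls (0 adjusted over the list alone), with the scavenger receptor Cd36 at 0.99 ± 0.32 and the macrophage antigen Adgre1 at 0.60 ± 0.22. They gave adjusted p = 1.420e-04, and adjusted p = 0.0892 with an estimated correlation. Basophil and mast cell markers had 10 of 10 readings above 0 (adjusted p = 2.300e-04, and adjusted p = 0.321 with an estimated correlation). The cytokine genes Tnf (-0.15 ± 0.18) and Il6 (0.35 ± 0.26) were not called.

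At an unadjusted limma p under 0.05, CpG-A + LIF vs CpG-A had 1200 of 19751 genes, a count that includes genes passing by chance. The 1 call was lost without each of the 6 arrays in turn, for Ifna12 at adjusted p-values from 0.0519 to 0.119, and was 0 with only the arrays compared. With the replicate as a block 12 genes were called.

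CpG-B + LIF vs CpG-B asked how LIF changes the CpG-B response (n = 3 and 3). Cell cycle and glycolysis genes leaned to higher readings as lists, and interferon-stimulated, plasmacytoid dendritic cell identity and cholesterol synthesis genes to lower ones, without a called member. Of the 6 lists called, 0 kept their call with an estimated correlation. Among single genes, the adhesion molecules Jaml (-0.94 ± 0.16) and Cdh1, which encodes E-cadherin (-0.85 ± 0.15), read lower, as did the semaphorin co-receptor Nrp1 (-0.77 ± 0.13), Arl14 (-0.98 ± 0.14), the ganglioside synthase St8sia1 (-1.07 ± 0.18) and Mctp2 (-0.78 ± 0.14). The oxysterol-binding protein Osbpl3 (0.82 ± 0.13), the neurofilament gene Nefh (0.69 ± 0.12) and Vmn1r174 (0.91 ± 0.15) read higher. These 9 genes had adjusted p-values from 0.0185 to 0.0443.

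In all, 12 genes were called in CpG-B + LIF vs CpG-B, and 19 with the replicate as a block. The 3 others, chosen after their values were seen, stayed open: the chemokine Xcl1 (-1.50 ± 0.25, or 1.82), the tight junction gene Cldn7 (1.22 ± 0.21, or -2.10) and Map2k3os (1.24 ± 0.16, or -2.08). Cell cycle had 27 of 29 nearest readings above 0 and 0 calls (3 adjusted over the list alone), with a median of 0.333. The replication helicase genes Mcm3 and Mcm4 read 0.62 ± 0.18 and 0.59 ± 0.17. The list gave adjusted p = 8.400e-10, and adjusted p = 0.206 with an estimated correlation. In glycolysis 15 of 17 readings were above 0 (1 called adjusted over the list alone; adjusted p = 0.00927, and adjusted p = 0.206 with an estimated correlation), with the lactate dehydrogenase gene Ldha at 0.62 ± 0.17. Interferon-stimulated genes had 38 of 43 readings below 0 and 0 calls (0 adjusted over the list alone), with Mx1 at -0.51 ± 0.14 and Herc6 at -0.54 ± 0.15. They gave adjusted p = 2.570e-10, and adjusted p = 0.292 with an estimated correlation. Plasmacytoid dendritic cell identity had 22 of 28 readings below 0 and 0 calls (7 adjusted over the list alone), with adjusted p = 9.480e-08, adjusted p = 0.0848 with an estimated correlation and fry adjusted p = 0.0179. Siglech read -0.70 ± 0.13 (adjusted p = 0.0603, and 0.0468 with the replicate as a block, in a range over alternatives of 0.0267 to 0.308), and Smim5 -0.98 ± 0.20 (adjusted p = 0.0831, and 0.0233 with the block). Cholesterol synthesis had 17 of 19 readings below 0 (adjusted p = 0.0024, and adjusted p = 0.554 with an estimated correlation), with Dhcr7, its last enzyme, at -0.49 ± 0.19. Oxidative phosphorylation had a median of 0.0942 (adjusted p = 0.0397, and adjusted p = 0.679 with an estimated correlation). Tnf (-0.07 ± 0.18), Il6 (0.46 ± 0.26), Ifna4 (-0.31 ± 0.32) and Ifnb1 (-0.21 ± 0.23) were not called.

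The calls in CpG-B + LIF vs CpG-B depended on single arrays. The count was 1 without CpG-B + LIF replicate 1, 1 without CpG-B replicate 2, 4 without CpG-B replicate 3, 5 without CpG-B + LIF replicate 3 and 7 without CpG-B replicate 1. It was 0 with only the arrays compared, and leaving out CpG-B + LIF replicate 1 ended all 9 named calls. Unfolded at the widest gap, St8sia1 read 0.03.

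The mean LIF effect over the 3 backgrounds asked what LIF does with and without CpG (n = 9 with LIF and 8 without). Genes of plasmacytoid dendritic cell identity leaned to lower readings as a list, and monocyte and macrophage markers to higher ones, with 0 of 21 of the latter called. Such a mean moves by 1.11 if 1 background is misread, so a direction is given only where all 3 readings are within the limit, and otherwise the mean with the largest reading exchanged is added. The identity genes Havcr1 (-0.73 ± 0.12), Smim5 (-0.70 ± 0.12), Sla2 (-0.61 ± 0.11), Upb1 (-0.59 ± 0.10) and the transcription factor Spib (-0.41 ± 0.09) read lower. Gapt (-0.79 ± 0.12) read lower too. Increases included the integrin Itgax, which encodes CD11c (0.77 ± 0.13), the complement regulator Cfp (0.71 ± 0.10), the sialyltransferase St6gal1 (0.62 ± 0.10) and Plscr3 (0.54 ± 0.09). Open in direction were the purinergic receptor P2ry13 (-1.07 ± 0.13, or 0.04), cyclin D1, Ccnd1 (-0.84 ± 0.10, or 0.27), the interferon-induced GTPase Gbp4 (-0.71 ± 0.08, or 0.40), the protease inhibitor Cst7 (0.96 ± 0.12, or -0.15) and the E-protein inhibitor Id2 (0.56 ± 0.10, or -0.54).

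For the mean LIF effect 151 genes were called, of which 41 read higher, 73 read lower and 37 stayed open. In plasmacytoid dendritic cell identity, 5 of 28 members were called, all lower (12 adjusted over the list alone), and 24 had nearest readings below 0, with a median of -0.174. The list gave adjusted p = 2.420e-09, adjusted p = 0.0346 with an estimated correlation and fry adjusted p = 0.00121. Siglech read -0.30 ± 0.08 (adjusted p = 0.0951). Monocyte and macrophage markers had 0 calls by limma over all genes and 6 adjusted over the list alone, with 17 of 21 nearest readings above 0 and a median of 0.184. They gave adjusted p = 6.080e-06, adjusted p = 0.0346 with an estimated correlation and fry adjusted p = 0.0114. In this list Cd36 read 0.78 ± 0.19, Msr1 0.48 ± 0.13 (or -0.63) and the growth factor receptor Csf1r 0.43 ± 0.12. The interferon regulator Irf7 (-0.53 ± 0.11), the antiviral gene Mx2 (-0.52 ± 0.12) and Cxcl10 (-0.60 ± 0.12) read lower, with adjusted p-values of 0.0348, 0.044 and 0.0248. Clec10a, a lectin of conventional dendritic cells, read -0.83 ± 0.17, while the plasma cell regulator Prdm1 and the mast cell receptor Kit read 0.58 ± 0.12 and 0.50 ± 0.11 higher. Some of these means were uneven over the backgrounds. In resting, CpG-A and CpG-B cells Prdm1 read 0.90, 0.08 and 0.75, Kit 1.02, 0.48 and 0.00, and Cxcl10 -1.06, -0.14 and -0.60.

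**Figure D2:**
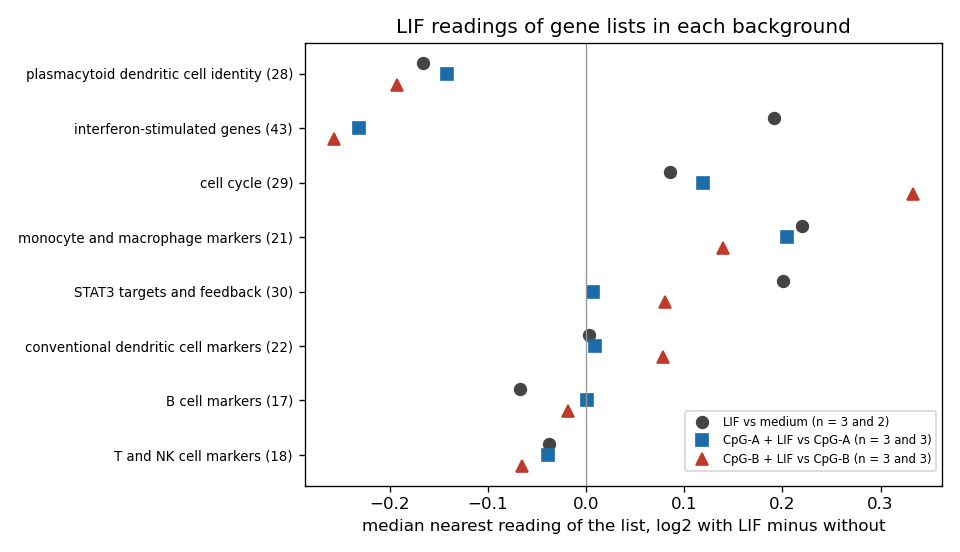
Median nearest reading (log2, with LIF minus without) of 8 gene lists in resting cells (n = 3 and 2), CpG-A cells and CpG-B cells (n = 3 and 3 each), with the number of genes in brackets. Plasmacytoid dendritic cell identity lies below 0 in all 3 backgrounds, at -0.166, -0.142 and -0.192, and interferon-stimulated genes at 0.191, -0.231 and -0.257.

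Other lists called for the mean LIF effect lost their call with an estimated correlation. Cell cycle had a median of 0.165 (adjusted p = 1.030e-06, and adjusted p = 0.28 with an estimated correlation) and cholesterol synthesis -0.114 (adjusted p = 0.00227, and adjusted p = 0.448 with an estimated correlation), both with 0 calls by limma. Interferon genes had a median of -0.301 and 1 call, open in direction (adjusted p = 7.120e-04, and adjusted p = 0.414 with an estimated correlation). The sign of that median is open, because 9 of 14 members are beyond the limit on direction in a background. Interferon-stimulated genes had -0.0806 and 2 calls (adjusted p = 0.00722, and adjusted p = 0.638 with an estimated correlation). STAT3 targets had 0.088 and 1 call (adjusted p = 0.00342, and adjusted p = 0.152 with an estimated correlation), glycolysis 0.0992 (adjusted p = 0.00611, and adjusted p = 0.152 with an estimated correlation), and basophil and mast cell markers 0.191 (adjusted p = 0.00722, and adjusted p = 0.446 with an estimated correlation). The remaining 18 lists were not called. Their medians were -0.00698 for conventional dendritic cells, 0.0945 for neutrophils, 0.0131 for B cells, -0.00674 for plasma cells, -0.0582 for T and NK cells, 8.430e-04 for erythroid cells, 0.0157 for apoptosis, -0.0154 for the unfolded protein response, 0.0263 for oxidative phosphorylation, 0.0572 for stress genes and 0.0156 for LIF receptor and JAK-STAT components. For immune programs they were 0.0108 for cytokines and chemokines, 0.0731 for co-stimulation and maturation, 0.0417 for MHC class II, -0.09 for MHC class I, -0.0594 for endosomal TLR signalling, 0.00143 for NF-kB targets (with a mean of -0.0228) and -0.123 for the E-protein and Id factor axis.

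Of 32 called genes of the naming rule followed for the mean LIF effect, 10 kept the call without each array in turn: Itgax, Cfp, St6gal1, Plscr3, P2ry13, Ccnd1, Gapt, Havcr1, Gbp4 and Upb1. Leaving out medium replicate 3 left 45 called genes and ended 19 of these calls. The count was 60 without medium replicate 1, 82 without CpG-B + LIF replicate 1, 81 without CpG-B replicate 2, 93 without CpG-B + LIF replicate 3, 87 without CpG-A + LIF replicate 3, and 35 when LIF was averaged over CpG-A and CpG-B alone. That average ended the calls of Havcr1 (-0.64, adjusted p = 0.0775; range over alternatives 0.00489 to 0.997) and Upb1 (-0.50, adjusted p = 0.0863; range 0.00167 to 0.93). Leaving out 1 array took 1 background reading past a size of 1.66 and so moved the means of Cst7 (-0.04 without medium replicate 1), Ifna12 (0.39 without CpG-A replicate 2; -0.65 with all arrays) and Saa3 (-0.38 without LIF replicate 3; 0.66 with all arrays). The readings behind them went from 1.60 to -1.39 (or 1.93), from -1.58 to 1.53 (or -1.79) and from 1.57 to -1.55 (or 1.78), a turn made by the fold. Unfolded at the widest gap P2ry13 read 0.78, Ccnd1 0.27, Upb1 0.15, Havcr1 0.01, St6gal1 0.06, Ifna12 0.46 and Saa3 -0.45.

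The responses to CpG with and without LIF shared more called genes than expected of independent calls. CpG-A + LIF vs LIF (n = 3 and 3) called 3430 genes, 1230 higher, 1440 lower and 760 open, and shared 2269 with CpG-A vs medium, against 573 if the calls were independent. Of the shared genes 566 read higher in both, 710 lower in both and 3 in opposite directions. CpG-B + LIF vs LIF (n = 3 and 3) called 5025 genes, 2070 higher, 1781 lower and 1174 open, and shared 2858 with CpG-B vs medium, against 966 if independent. It also shared 1913 with CpG-A vs medium, against 840, of which 346 read higher in both, 440 lower in both and 181 in opposite directions. In the CpG-A case 14 of 18 MHC class I genes (adjusted p = 1.300e-09, and adjusted p = 0.0594 with an estimated correlation) and 16 of 24 unfolded protein response genes (adjusted p = 7.880e-12, and adjusted p = 0.0594 with an estimated correlation) were called, with medians of 0.629 and 0.631. In the CpG-B case 15 of 18 MHC class I genes were called, 12 higher and 3 open (adjusted p = 1.480e-10, and adjusted p = 0.0792 with an estimated correlation). Oxidative phosphorylation had 10 of 28 called there, all higher (10 adjusted over the list alone; adjusted p = 0.00138, and adjusted p = 0.475 with an estimated correlation).

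Whether LIF acts on the genes that a CpG raises was tested on genes chosen with the other CpG, so that no array served both steps. On 715 genes raised by CpG-B, LIF under CpG-A had a median reading of 0.044, with 311 genes lower (camera adjusted p = 0.166 over both sets). On 493 genes raised by CpG-A, LIF under CpG-B had a median of -0.029, with 272 genes lower (camera adjusted p = 0.0262 over both sets). The median was -0.012 without CpG-B replicate 1, which ended that call. Membership of both sets rests on called nearest readings of at least 1, with no upper limit, so the direction is open for most members. Many genes in the sets may have been lowered. The medians therefore do not tell how LIF acts on genes that a CpG truly raised.

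The interactions asked whether LIF acts differently under CpG than in resting cells. Each is the difference of 2 nearest readings, and so can pass 1.66 in size. A gene can thus be called on the larger of its 2 readings. For CpG-A 10 genes were called and for CpG-B 27 (29 and 50 with the replicate as a block), and Socs3 was in both, at 1.67 ± 0.24 (or -1.65) and 1.60 ± 0.24 (or -1.72). Interferon-stimulated genes had median interactions of -0.42 with CpG-A (adjusted p = 6.070e-16, and adjusted p = 0.276 with an estimated correlation) and -0.552 with CpG-B (adjusted p = 3.940e-15, and adjusted p = 0.263 with an estimated correlation). The antiviral gene Oas3 was called in neither interaction (-1.26 ± 0.23, or 2.06, with adjusted p = 0.0532 for CpG-A, and adjusted p = 0.096 for CpG-B). The LIF effects under CpG-A and CpG-B did not differ for any single gene at the threshold: limma called 0 genes, and 0 with the replicate as a block. At an unadjusted limma p under 0.05 there were 1009 genes, about what that threshold passes among 19751 genes without any effect. Across genes, which are not independent replicates, the LIF effects correlated at r = 0.173 between CpG-A and CpG-B, 0.13 between resting cells and CpG-A and -0.0031 between resting cells and CpG-B.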

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

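The tests chosen only after the result was seen were those of a lower share of plasmacytoid dendritic cells, of signal shared between Ifna genes, of the direction of the interferon readings, of their size without each array, of the direction of the identity list at the widest gap, of splits that keep the LIF and medium groups, and of single arrays behind the count of LIF genes in resting cells.

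Interactions of LIF with CpG were called for 10 genes with CpG-A and for 27 with CpG-B, on differences that were not folded again. For some of these genes the other reading is the smaller one, and whether they pass at it was not tested. Examples with CpG-A are Fgl2 at 2.14 ± 0.34 (or -1.18) and Eid3 at -1.94 ± 0.31 (or 1.38). With CpG-B they include Xcl1 at -1.97 ± 0.38 (or 1.36) and Ddx60 at -1.88 ± 0.34 (or 1.44). For the rest the difference is the smaller reading. Both counts may therefore depend on not folding again. Of 100 splits of the arrays within backgrounds, 7 called at least 10 genes in the CpG-A interaction (highest other 125). In the CpG-B interaction 3 of 100 splits called at least 27 (highest other 91). Most splits mix LIF with medium arrays and so remove the resting LIF effect itself, which makes neither share a test of an interaction. Splits that call 125 or 91 genes, several times the real counts, point to a structure of the samples, here the LIF and medium groups themselves. Of the other splits that keep these groups whole and mix only the CpG arrays, 6 of 12 reached the real count for CpG-A and 2 of 6 for CpG-B. Such splits keep the resting LIF effect and so hold a difference between backgrounds by construction. Neither kind of split can therefore test the interactions, and chance is not excluded for either. These splits and counts do not use the replicate number as a pair; with the replicate as a block the interactions called 29 and 50 genes, which the splits did not test. Of 87 and 93 splits that mix LIF with medium arrays, the highest counts were 7 and 8, and 0 reached the real count. All 10 genes of the CpG-A interaction, and 21 of 27 in the CpG-B interaction, were also called in LIF vs medium. The count was 2 without medium replicate 3 and 31 without LIF replicate 2 for CpG-A, and 5 without medium replicate 3 for CpG-B.

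Socs3, the feedback inhibitor of LIF signalling, had an interaction of 1.67 (or -1.65) with CpG-A and 1.60 (or -1.72) with CpG-B. Its other probe set gave -0.93 and -0.84, and the call for CpG-A was lost without medium replicate 1 (1.39), medium replicate 3 (-1.37, or 1.96), CpG-A replicate 1 (1.60) and CpG-A + LIF replicate 1 (1.53). For CpG-B it was lost without medium replicate 1 (1.32) and medium replicate 3 (-1.44, or 1.88). Cd69, an early activation marker, had an interaction of -1.67 (or 1.65) with CpG-B, with calls lost without medium replicate 1 (1.22, or -2.11) and medium replicate 3 (-1.24, or 2.09). The turns of sign of Socs3 and Cd69 are made by the fold, as their resting readings passed a size of 1.66. Pygb, a glycogen phosphorylase, read 0.96 ± 0.18 and Moxd1 -1.08 ± 0.20 in the CpG-B interaction, and both calls were lost without medium replicate 1 (1.01 and -1.15) and without medium replicate 3 (adjusted p = 0.181 for each, the highest over their alternatives, whose lowest were 0.0204 and 0.018). Both were also lost without CpG-B replicates 1, 2 and 3 and CpG-B + LIF replicates 1 and 2, that of Pygb without LIF replicate 2, and that of Moxd1 without LIF replicates 1 and 3.

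Plasmacytoid dendritic cell identity genes had mostly nearest readings below 0 with LIF averaged over the 3 backgrounds, with a mean of -0.195. Of 100 splits 1 (the real one) gave a mean as low, against -0.158 in the lowest other. This share under 0.05 argues against chance but does not exclude it, and the splits did not use the replicate number as a pair. Readings of the wrong direction stay open as a cause. Unfolding at the widest gap moved only 3 of 28 members, and many other genes, by more than 0.277. For the other members the result was close to fixed in advance. The setting also rests on the same digits without their decimal mark, so it cannot decide the direction. The list mean stayed at -0.155 (SE over members 0.0474), with 22 of 28 members below 0, camera adjusted p = 2.690e-06, and adjusted p = 0.0477 with an estimated correlation, close to the threshold. Single members stay open, as Havcr1 (0.01) and Upb1 (0.15) turned. The test planned first decides nothing: the unadjusted limma camera p was 1.340e-12 without Cd209d, the 1 member with a reading beyond the limit, but Cd209d reads against the list, so leaving it out could not weaken the list. A lower share of plasmacytoid dendritic cells in the LIF cultures would raise markers of other cells alike only if those cells were of all these kinds. Monocyte and macrophage markers had a mean of 0.223 (21 genes) and markers of B, T, NK and erythroid cells -0.00859 (46 genes). The difference was 0.232 (permutation p = 1.800e-04 over genes, which are not independent replicates). A lower share cannot be told apart from a change within the cells. Levels over background are lost, the second set may be silent, and the kinds of other cells are unknown. The sort for Siglec-H and B220 would remove most other cells. An effect of LIF on the identity program, the difference the design names, stays open as a hypothesis.

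Interferon genes had mostly nearest readings below 0 with LIF under CpG-A, with adjusted p = 5.730e-11 for the list, and adjusted p = 0.0892 with an estimated correlation. Signal shared between near-identical Ifna transcripts stays open as a cause. Ifnb1, a distinct gene, read -1.22 (or 2.10) at an unadjusted limma p of 6.060e-05, and was not called after adjustment (0.0998). The other members outside the Ifna family, Ifne (-0.01), Ifnk (0.28) and Ifnl2 (-0.44), were not called either. Readings of the wrong direction stay open, since 4 of 14 members had a reading within the limit on direction and below 0, and both directions cannot be told apart for the rest. A dependence on 1 array also stays open. The median was -0.10 without CpG-A + LIF replicate 1 and -0.23 without CpG-A replicate 2, against -1.20 with all arrays, but in each of these 3 members passed a size of 1.66 and changed sign through the fold, which voids the test. The median size of the readings was 0.77 to 1.40 over the 6 leave-outs, against 1.26 with all arrays. An effect of LIF on interferon production may underlie the pattern and stays open as untested beyond this.

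More genes were called for LIF in resting cells (160) than under CpG-A (1) or CpG-B (12). That 1 array of the medium or LIF groups made the whole difference cannot be told apart. The lowest count over the 5 leave-outs was 16 (without medium replicate 3), and its margin over 12 is no more than the 4 unchanged genes that simulated data called. The medium group has only 2 arrays. Fewer LIF effects in CpG-treated cells may be biological. The interactions, with 10 and 27 genes, ask whether the LIF effect on a gene differs, in either direction, and do not count LIF effects. They use the same medium and LIF arrays as the 160 calls, so they are no independent test of fewer effects. The splits could not test chance for the interactions, so chance was excluded for neither.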

How the results depend on the processing

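Chosen after seeing the data were the widest-gap unfolding, the robust variance prior and the narrower set of raised genes. The average over CpG-A and CpG-B alone was chosen then too. So was the limit to genes whose arrays could be placed within 3.16-fold by choice of decimal place. The dim probe set filter, repeated quantile normalization, the variance trend and the larger fold for raised genes were not run, since they need the lost levels. Signal over background is unknown, so noise from silent genes could not be set apart. Alternatives were followed for a part of the genes of the naming rule, picked after their values and before the alternatives were run; the text leaves some of them out. Of 4142 values of these genes under the alternatives, 3639 kept their side of the threshold, 457 lost the call, 32 gained it and 14 reversed, which was counted only for called values of at most 1.11 in size. A shorter selection, made after the alternatives were run, had left out some reversed genes and was withdrawn. Counts not named here stayed within 1.5 times. The cause was not tested except where a setting tests fewer genes or uses fewer arrays.

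With an added log2 difference of at least 1, a stricter criterion by construction, counts were 1162 for CpG-A vs medium, 1357 for CpG-B vs medium, 78 for LIF vs medium, 4 for CpG-B + LIF vs CpG-B, 634 for CpG-A vs CpG-B, 1019 for CpG-A + LIF vs LIF, 1527 for CpG-B + LIF vs LIF and 1 for LIF averaged. The next counts used only genes whose arrays could be placed within 3.16-fold by choice of decimal place, fewer genes by construction. They were, in the same order, 1879, 2124, 13, 2, 1292, 1851, 3101 and 14. Counts were 0 there for CpG-A + LIF vs CpG-A and both interactions. With only the arrays compared, limma called 17 in LIF vs medium, 0 in CpG-A + LIF vs CpG-A, 0 in CpG-B + LIF vs CpG-B, 0 in the CpG-A interaction and 17 in the CpG-B interaction, against 2036, 1200, 1529, 1388 and 1949 genes at an unadjusted p under 0.05 with all arrays.

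The replicate block gave 12 for CpG-A + LIF vs CpG-A, 19 for CpG-B + LIF vs CpG-B, 230 for LIF averaged, 29 and 50 for the interactions. The main tests did not take the shared number as a pair. Correlations across genes for CpG-A with CpG-A + LIF were 0.075, 0.170 and 0.015. Yet 14 of 17 arrays had their best match in other groups under their own number, a hint from the data. Array weights gave 25 for CpG-B + LIF vs CpG-B. Unfolded at the widest gap, counts were 9 for CpG-A + LIF vs CpG-A, 36 and 52 for the interactions, and 8 for LIF under CpG-A minus LIF under CpG-B. LIF averaged over CpG-A and CpG-B alone called 35. LIF under CpG-A on genes raised by CpG-B with the narrower set had a median of 0.045 and passed the threshold. Of 88 list calls over all comparisons, 5 held with an estimated correlation, 63 lists were called by fry and 93 by camera with the block.

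Leaving out 1 array gave 2128 (without medium replicate 1) to 2941 for CpG-A vs medium, 2451 (without medium replicate 3) to 3393 for CpG-B vs medium, 16 to 139 for LIF vs medium, 0 to 1 for CpG-A + LIF vs CpG-A, 1 to 9 for CpG-B + LIF vs CpG-B, 1909 to 2279 for CpG-A vs CpG-B, 2824 to 3115 for CpG-A + LIF vs LIF, 4092 to 4638 for CpG-B + LIF vs LIF, 45 (without medium replicate 3) to 170 for LIF averaged, 1 (without CpG-A replicate 1) to 31 (without LIF replicate 2) for the CpG-A interaction, 5 (without medium replicate 3) to 37 for the CpG-B interaction, and 0 to 2 for LIF under CpG-A minus LIF under CpG-B. Medians were 0.020 to 0.053 for LIF under CpG-A on genes raised by CpG-B and -0.047 to -0.012 for the converse.

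Reversed at the widest gap were Tnf in CpG-A vs medium (2.31), Cd300a in LIF vs medium (-1.16), St8sia1 in CpG-B + LIF vs CpG-B (0.03), and Cd300a (-0.03), Gria3 (-0.08), Saa3 (-0.45), Ifna12 (0.46), P2ry13 (0.78), Ccnd1 (0.27), Havcr1 (0.01) and Upb1 (0.15) in LIF averaged. Cst7 in LIF averaged read -0.04 without medium replicate 1, and up to 1.02 without CpG-B + LIF replicate 3. Saa3 in LIF averaged read -0.38 without LIF replicate 3, and up to 0.71 without CpG-B + LIF replicate 2. Ifna12 in LIF averaged read 0.39 without CpG-A replicate 2, and down to -0.70 without CpG-B + LIF replicate 3. In these 3 turns 1 background reading passed a size of 1.66, which moves a mean of 3 by about 1.11.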

Other observations

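The splits of the arrays were planned, and the check that readings add up was chosen after seeing the data.

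Further lists were called for CpG with LIF present. Some of them were also called for the same CpG without LIF, and these comparisons do not tell whether LIF changes the response. In CpG-A + LIF vs LIF, inflammatory cytokines and chemokines had 15 of 30 members called (19 adjusted over the list alone), 9 higher, 1 lower and 5 open, with adjusted p = 0.0259, and adjusted p = 0.419 with an estimated correlation. Co-stimulation and maturation genes had 10 of 24 called (10 adjusted over the list alone), 3 higher and 7 open, with adjusted p = 9.440e-04, and adjusted p = 0.198 with an estimated correlation. MHC class II genes had a median of -0.41 and cell cycle genes -0.379, both at adjusted p = 0.0259, with adjusted p = 0.516 and adjusted p = 0.629 with an estimated correlation. In CpG-B + LIF vs LIF, 4 of 10 basophil and mast cell markers were called, all lower (4 adjusted over the list alone), with adjusted p = 0.0448, and adjusted p = 0.488 with an estimated correlation. The unfolded protein response had 17 of 24 called there (18 adjusted over the list alone; adjusted p = 6.490e-05, and adjusted p = 0.338 with an estimated correlation), and co-stimulation genes 15 of 24 (15 adjusted over the list alone; adjusted p = 0.0448, and adjusted p = 0.475 with an estimated correlation).

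For a difference between the LIF effects under CpG-A and CpG-B, camera at the preset correlation called 4 lists. Of these, 0 kept their call with an estimated correlation, and directional fry called 0 lists. The 4 were interferon genes (median difference -0.901, of open sign because 9 of 14 readings under CpG-A are beyond the limit on direction; adjusted p = 1.590e-05, and adjusted p = 0.657 with an estimated correlation), basophil and mast cell markers (0.394; adjusted p = 7.390e-05, and adjusted p = 0.657 with an estimated correlation), cell cycle genes (-0.225; adjusted p = 0.00308, and adjusted p = 0.751 with an estimated correlation) and MHC class II genes (0.157; adjusted p = 0.027, and adjusted p = 0.751 with an estimated correlation).

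Checks on other groupings of the arrays were made for comparisons of 3 with 3 arrays, which have 10 splits and so cannot give a share under 0.05. In CpG-A vs CpG-B the real split called 2560 genes and the highest other split 0, and 1 split of 10 reached the real count. In CpG-A + LIF vs LIF the values were 3430 and 1, in CpG-B + LIF vs LIF 5025 and 0, and in CpG-B + LIF vs CpG-B 12 and 3, each with 1 split reaching the real count. In CpG-A + LIF vs CpG-A the real split called 1 gene, 3 of the 10 splits called as many, and the highest other called 2. For LIF averaged over the 3 backgrounds 1 of 100 splits, the real one, reached 151 genes (highest other 31), a share under 0.05 that argues against chance. The splits did not use the replicate number as a pair. For LIF under CpG-A minus LIF under CpG-B the real count was 0, which all 100 splits reach (highest other 8).

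Across the series, readings of 3 comparisons that must add up (CpG-A vs medium, CpG-B vs medium, CpG-A vs CpG-B) failed to do so for 372 of 5606 genes called in any of them (6.64%). Lifr and Siglech are among these genes. Of 4 sex-linked genes measured, 0 were called by limma in 11 comparisons and 2 in CpG-B + LIF vs LIF, with a largest difference of 0.87 and a lowest adjusted p of 9.280e-04. LIF replicate 2 had the widest spread around its group mean (SD 0.213 on the log2 scale).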
